A study of Mus musculus with 12 samples.

How the data were processed

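The study measured RNA from CD11c+ cells, a fraction rich in dendritic cells, that were pulled from mouse spleens with magnetic beads. Per the labels, 100 ng of total RNA per sample was amplified, labelled with biotin and hybridised to its own Illumina MouseWG-6 v2 array. Arrays fell into 4 groups of 3: ApoE-/- or Bl6, each on normal chow or a high-cholesterol diet. Neither a batch nor a chip is named for any array, and the running numbers in the titles pair no samples. The labels do not say that the samples of a group are separate mice, so every p-value measures the spread between these samples, which may be technical.

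One deposited table gives, per the file headers, a signal for each of 46237 probes on each array, and its values are a linear intensity that was neither background-subtracted nor scaled between arrays. Beside each intensity the deposited table gives a detection p-value, which is small where a probe lies above background. The other deposited table holds log2 values. Each of its columns equals the log2 of 1 column of intensities plus a constant between 0 and 0.443, with a spread of the difference of at most 1.9e-04 across probes. It was therefore scaled per array, without quantile normalisation and without subtracting background; how the constants were set is not given in the sources used here. The medians of its columns for samples 1 to 12 were 6.91, 6.98, 7.12, 6.90, 6.99, 6.90, 6.87, 6.93, 6.85, 6.91, 6.82 and 6.88 on the log2 scale, so its columns were not centred on a shared median.

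Both tables name the arrays, and they differ for the knockout. In 6 of the 12 log2 columns, all from Bl6 samples, the values came from the array of the same name. The other 6 columns, all from ApoE-/- samples, held the values of the other diet's arrays, with samples 1, 2 and 3 exchanged for 4, 5 and 6. Which table is right cannot be told from the files. The intensity table's names were used throughout, and each affected comparison is also given with the ApoE-/- diets exchanged.

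Intensities were processed with limma 3.58.1 in R 4.3.3. Background was corrected by the normexp model of the nec function, with the mean and SD of the negative controls inferred from the detection p-values and an offset of 16. Arrays were then quantile-normalised and put on the log2 scale. Tests used the 26390 probes with a detection p under 0.05 on at least 3 of the 12 arrays. One linear model with 4 group means was fitted to all arrays, with 8 residual degrees of freedom, and limma's empirical Bayes step moderated the variances (prior degrees of freedom 3.42). Contrasts were the genotype effect on each diet and averaged over both, the diet effect in each genotype and averaged over both, and the interaction. The moderated tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over all tested probes. A probe or gene is said to rise, fall or change only where its adjusted p was under 0.05.

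Gene symbols came from the platform's probe list, which gave 1 symbol for 35784 probes, several for 0 and none for 10453. Symbols were updated through the GRCm38.p6 gene table: 28620 probes matched by gene number, 2637 by transcript, 2128 by symbol and 2399 not at all, and 937 symbols changed. The tested probes named 14326 genes, of which 13125 had a place in that table. Each gene was represented by its brightest tested probe. Genes within 20 Mb of Apoe on chromosome 7 were called near Apoe, and their share of the calls was tested with a two-sided Fisher's exact test. In the text, ± is the standard error of the model unless SD is stated.

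Cell types and pathways were followed with 33 gene lists. Each was tested with limma's camera (competitive, two-sided, preset correlation 0.01), adjusted over the lists of a contrast. Results of camera with an estimated correlation are given beside the calls, and those of fry for a few lists only. The fry p-value tests whether a list's genes moved, on balance, one way, and compares them with no other genes. Counts of list members that passed are given over all probes and adjusted over the list alone. The groups, contrasts, tests, lists and the rule for naming genes were fixed before the data were examined. The rule named Apoe, the 6 largest rises and 6 largest falls past the threshold, and up to 2 passing members per list. It also named the best member of 6 chosen lists where none passed, and the 5 genes with the smallest p where fewer than 5 named genes passed. Predicted models and clone names were passed over; symbols that begin with a digit were treated as clone names too, a slight extension of the rule. Other list members printed with values were chosen after their values were seen.

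The steps were tested on simulated data with the moderated spread that the model gave the real probes. For the diet effect in Bl6 samples, 71 of 100 probes changed by a log2 of 1 and 97 of 100 changed by 2 were called, with 6 false calls among 26390 probes. For the genotype effect averaged over diets, 91 of 100 and 99 of 100 were called, with 11 false calls. In a simulation of the diet effect in Bl6 samples, 1 of 1 raised lists was called and 0 of the others. Simulated probes were drawn independently and the lists were random, so this does not test calls on lists whose genes vary together. Nor do the false calls hold for arrays that share a structure, which the simulation left out. In the real data a split of the Bl6 arrays that does not follow diet called 169 probes.

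Alternatives were no background correction, median scaling, the deposited log2 values, no filter on dim probes, a stricter filter (detection p under 0.01 on at least 6 arrays), and only the groups compared. Further ones were a variance trend with robust estimation, array weights, probes averaged per gene, and each array left out in turn. Exchanging the ApoE-/- diets, and using the log2 values under the intensity table's names, were added after seeing the data. A block for the chip could not be fitted, since the files name no chip. Figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision of every comparison.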

Results

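RNA of CD11c+ spleen cells was measured in 12 samples: 3 each from ApoE-/- mice on normal chow, ApoE-/- mice on a high-cholesterol diet, Bl6 mice on chow and Bl6 mice on the high-cholesterol diet. Median signal per array ran from 102 to 120 intensity units, against a background mean of 95.8 to 111. The median probe therefore lay 1.07 to 1.08 times above background, and 22077 to 23245 probes per array (47.7% to 50.3%) were detected. Arrays of the same group differed with an SD of 0.354 to 0.426 in log2 units across tested probes, and arrays of any pair of groups with 0.341 to 0.475. The series title places apolipoprotein E from CD11c+ cells in atherosclerosis, so the comparisons ask what the knockout and the diet each changed in these cells.

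The deposited tables name the diets of the 6 ApoE-/- arrays in opposite ways. Samples 1, 2 and 3 are ApoE-/- chow arrays in the intensity table, and their values stand under samples 4, 5 and 6, the high-cholesterol diet, in the log2 table; the 6 Bl6 arrays carry the same names in both. Which is right cannot be told from the files. Values below follow the intensity table, and those with the ApoE-/- diets exchanged follow the log2 table's names.

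Apoe, the gene disrupted in the knockout, encodes an apolipoprotein, a protein of the lipoprotein particles that carry cholesterol. In the 6 ApoE-/- samples its probe read 5.52, 5.93, 5.50, 5.61, 5.80 and 5.75 in log2 units. In the Bl6 chow samples it read 12.18, 12.33 and 12.26, and in the Bl6 high-cholesterol samples 13.11, 13.29 and 13.04. The fall with genotype was -7.01 ± 0.10 averaged over diets (adjusted p = 4.0e-12, n = 6 per genotype), -6.61 ± 0.14 on chow and -7.42 ± 0.14 on the high-cholesterol diet. Where the probe lies relative to the deleted part of the gene is not given in the sources used here. Between diets Apoe read 0.89 ± 0.14 higher in Bl6 samples, which missed the threshold (adjusted p = 0.0753), and 0.07 ± 0.14 higher in ApoE-/- samples (adjusted p = 1).

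Genotype also parted the arrays by sex-linked genes. Xist, which silences an X chromosome in female cells, read 9.75 to 10.88 in the 6 Bl6 samples and 4.17 to 4.39 in the 6 ApoE-/- samples. Of the Y-linked genes, Eif2s3y read 9.75 to 10.44 in ApoE-/- and 4.11 to 4.41 in Bl6 samples, and Kdm5d read 7.42 to 7.67 and 4.18 to 4.63. These readings are from the brightest probe; that of Xist was not detected in any ApoE-/- sample, nor Eif2s3y or Kdm5d in any Bl6 sample. With each undetected value raised to the dimmest detected probe of its array, Xist was at least 59.8-fold lower in the knockout, Eif2s3y at least 49.0-fold higher and Kdm5d at least 8.12-fold higher. All 12 arrays followed this pattern, so every genotype comparison is also a comparison of these sex-linked states.

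**Figure D1:**
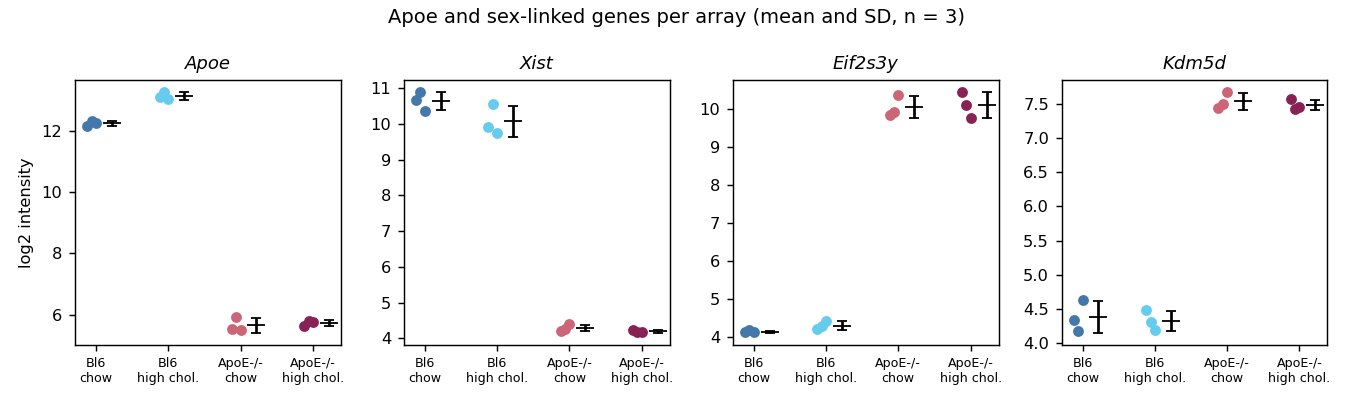
Log2 intensity (y axis) of Apoe, Xist, Eif2s3y and Kdm5d on each array, by group (x axis), with the mean and SD of 3 samples. Apoe stayed at or under 5.93 in ApoE-/- samples and at or over 12.18 in Bl6 samples.

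Averaged over both diets, genotype changed 423 probes, 172 up and 251 down (4166 at an unadjusted p under 0.05), which named 342 genes. Leaving out 1 array gave 142 (without sample 1) to 605 (without sample 7). This contrast is the same under both tables' names, since each genotype's 6 arrays are the same. After the Y genes, the largest rises were in Ltf, the iron-binding lactoferrin of neutrophil granules (1.76 ± 0.25), Camp, an antimicrobial peptide of the same granules (1.68 ± 0.22), and Gzmk, a granzyme of T cells (1.67 ± 0.17, detected on 5 of 6 Bl6 arrays). Zfp30, a zinc-finger gene, rose as well (adjusted p = 1.1e-05), from a level detected on 1 of 6 Bl6 arrays. After Apoe and Xist, the largest falls were in Apoc2, an activator of lipoprotein lipase (-3.60 ± 0.16), Psmd8 of the proteasome (-3.22 ± 0.08), Clasrp, which acts in splicing (-2.49 ± 0.11), and Zfp420. Zfp420 was undetected in every ApoE-/- sample and at least 4.37-fold lower there. Adjusted p-values of these genes ran from 0.00725 for Ltf to 9.0e-10 for Psmd8. Apoc2, Psmd8 and Clasrp each had another tested probe that did not pass, with values of 0.38, 0.25 and -0.06.

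Many of these genes neighbour Apoe. Of 281 changed genes (by their brightest probes), 35 lay within 20 Mb of Apoe on chromosome 7 in GRCm38.p6, out of 389 tested there, and 12 of them rose and 23 fell. Fisher's exact test on the 13125 placed genes gave an odds ratio of 5.62 (confidence interval at R's default level 3.76 to 8.20, two-sided p = 2.8e-14). Apoc2 and Clasrp sit a few genes from Apoe, and Psmd8, Zfp30 and Zfp420 further along the same stretch. Other changed neighbours were Pglyrp1, a peptidoglycan-binding protein of neutrophil granules (1.53), Cd177, a neutrophil surface protein (1.37), Nfkbib, an inhibitor of NF-kappaB (1.11), Fbxo46 (-1.54) and Mrps12 (-0.98); Nfkbib, Fbxo46 and Mrps12 were chosen after their values were seen. The rest of chromosome 7 held 11 of the changed genes, the X chromosome 10, the Y chromosome 2, the other autosomes 197, and 26 had no place. X-linked genes were not over-represented (odds ratio 1.19, confidence interval 0.559 to 2.25, Fisher's exact two-sided p = 0.594).

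**Figure D2:**
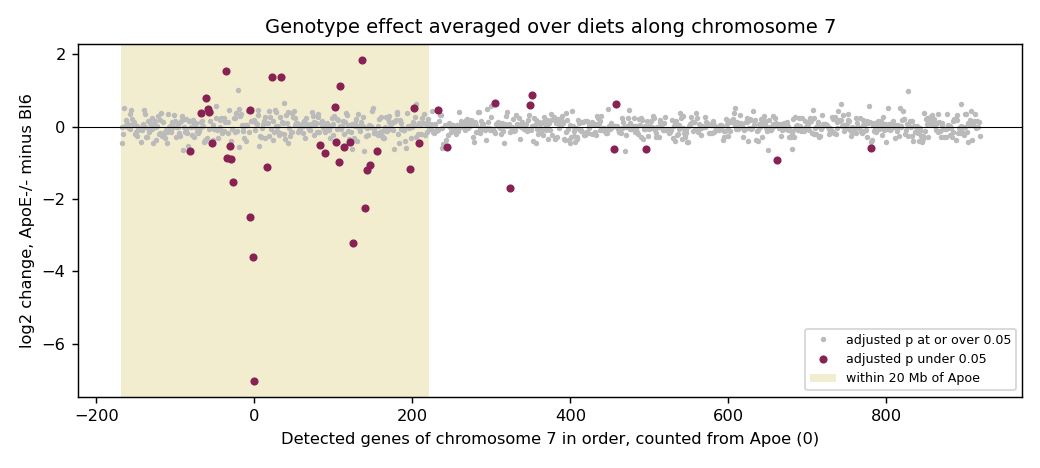
Genotype effect averaged over diets (y axis, log2, ApoE-/- minus Bl6) for the detected genes of chromosome 7 in their order, counted from Apoe (x axis). Dark points are genes with an adjusted p under 0.05, of which 35 lie in the shaded stretch of 389 genes within 20 Mb of Apoe.

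Neutrophil genes were higher in the ApoE-/- samples. Of the 16 measured genes of the neutrophil and granulocyte precursor list, 10 rose and 0 fell over all probes, 15 rose adjusted over the list alone, and all 16 had values above 0. S100a8, an abundant calcium-binding protein of neutrophils, read 13.03 to 13.62 in the 6 ApoE-/- samples and 11.98 to 12.66 in the 6 Bl6 samples, a rise of 1.10 ± 0.14 (adjusted p = 0.00283). Its partner S100a9 rose by 1.19 ± 0.15. The granule genes Lcn2 (1.57 ± 0.24), Ngp (1.42 ± 0.25) and Mmp9 (0.83 ± 0.12) rose with them. Elastase, Elane, read 0.60 ± 0.19 higher and did not pass (adjusted p = 0.151), and proteinase 3, Prtn3, 0.28 ± 0.20 (adjusted p = 0.532). The list's median was 1.03 and its mean 1.01; camera gave an adjusted p of 1.1e-17, and the adjusted p = 0.0916 with an estimated correlation. By fry the genes moved up on balance (adjusted p = 3.9e-04). The ApoE-/- arrays were not alike: the list's mean was 7.66 and 7.63 on samples 3 and 5, against 8.04 to 8.18 on the other 4 and 6.84 to 7.19 on the Bl6 arrays. Ltf read 8.27 and 8.21 on samples 3 and 5 and 9.25 to 9.43 on the other 4. Cd177 is both a list member and a neighbour of Apoe, and its other probe, undetected in every Bl6 sample, rose as well (adjusted p = 0.0374).

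**Figure D3:**
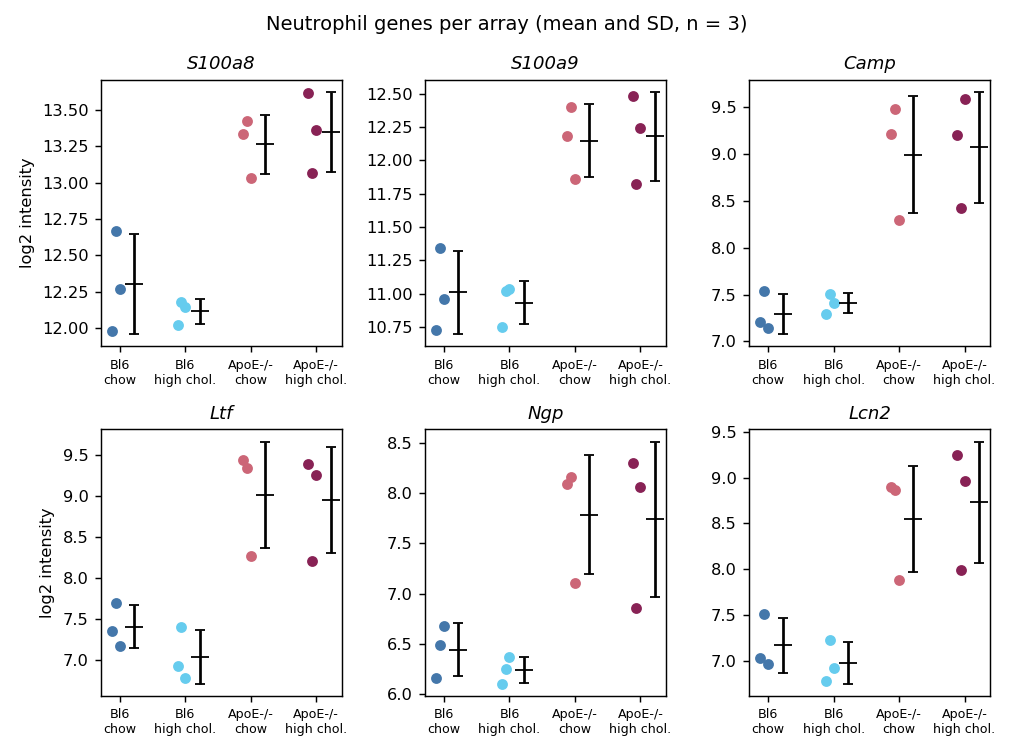
Log2 intensity (y axis) of S100a8, S100a9, Camp, Ltf, Ngp and Lcn2 on each array, by group (x axis), with the mean and SD of 3 samples. All 6 ApoE-/- samples of S100a8 (13.03 and above) lay over all 6 Bl6 samples (12.66 and below).

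A few genes of the T cell, NK cell and monocyte lists rose. In the T cell list, 3 of 16 genes rose, 0 fell, and 10 rose and 1 fell adjusted over the list alone. Thy1, a surface protein of T cells, rose by 0.71 ± 0.12, Cd6 by 0.67 ± 0.11 and Cd8b1 by 0.58 ± 0.11; 2 of the 3 other Cd6 probes also rose. The list's median was 0.37 (camera adjusted p = 6.8e-05; adjusted p = 0.183 with an estimated correlation). In the NK cell list, Il2rb, a receptor chain for interleukin 2, was the 1 gene of 16 that rose (0.56 ± 0.10), with 9 adjusted over the list alone, and the median was 0.33 (camera adjusted p = 7.4e-04; adjusted p = 0.674 with an estimated correlation). In the monocyte list F13a1, a coagulation factor made by monocytes, rose by 0.94 ± 0.17 (1 of 11; 3 rose and 1 fell adjusted over the list alone), and the list was not called (camera adjusted p = 0.136). The proliferation list had 0 of 24 genes past the threshold and a median of 0.23 (camera adjusted p = 0.00173; adjusted p = 0.69 with an estimated correlation).

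Macrophage and B cell genes read lower. C1qa, a complement gene of tissue macrophages, fell by 0.46 ± 0.08 (adjusted p = 0.0231), and Cd68, a lysosomal macrophage protein, by 0.57 ± 0.10 (adjusted p = 0.0251). These were 2 of 19 genes of the red pulp and marginal zone macrophage list; 9 fell adjusted over the list alone. The list's median was -0.29 and its mean -0.13 (camera adjusted p = 3.9e-05, and adjusted p = 0.238 with an estimated correlation). Vsig4 at 0.83 ± 0.49 and Marco at 0.71 ± 0.61 read the other way without passing. By array, the list's mean was 10.86 to 11.19 in ApoE-/-, 10.92 to 11.15 in Bl6 chow and 11.22 to 11.31 in Bl6 high-cholesterol samples. Only the last group lay apart by this mean, whereas C1qa and Cd68 each read lower on every ApoE-/- array than on any Bl6 array. In the B cell list 0 of 15 genes passed, also adjusted over the list alone, with a median of -0.24 (camera adjusted p = 2.0e-04; adjusted p = 0.531 with an estimated correlation). The lower reading rested on 3 Bl6 arrays: the list's mean was 10.28, 10.07 and 9.92 on samples 8, 9 and 11, but 9.63, 9.63 and 9.61 on samples 7, 10 and 12, within the 9.46 to 9.78 of the ApoE-/- arrays. Erythroid genes showed no call, with 0 of 13 passing and a median of -0.03 (camera adjusted p = 0.631).

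Dendritic cell genes changed little. Itgax, which encodes CD11c, read 0.14 ± 0.12 higher in the knockout (adjusted p = 0.626). In the CD11c and dendritic cell core list 1 of 11 genes rose, Csf2rb, a receptor chain for GM-CSF (0.69 ± 0.14), whose 2 other probes read 0.72 and 0.59 without passing; 1 rose and 1 fell adjusted over the list alone. Cadm1, an adhesion molecule of type 1 conventional dendritic cells, fell by 0.51 ± 0.11 (1 of 13 genes; camera adjusted p = 0.315). In the list of type 2 conventional dendritic cells Tbx21, a T-box factor, rose by 0.49 ± 0.10 (1 of 12, or 4 adjusted over the list alone). That list's median was 0.12 (camera adjusted p = 0.043, and adjusted p = 0.218 with an estimated correlation). Which cells the Tbx21 RNA came from was not tested, and camera called the T cell and NK cell lists up in the same contrast. The plasmacytoid list had a median of -0.11 (camera adjusted p = 0.0475; adjusted p = 0.531 with an estimated correlation), with Klk1, a kallikrein, down by -0.56 ± 0.12 as its 1 change among 14 genes. Of 14 MHC class II genes 0 passed; the transactivator Ciita read 0.26 ± 0.09 (adjusted p = 0.214), and the maturation gene Cd83 read -0.37 ± 0.09 (adjusted p = 0.0575).

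Among lipid genes, Plin2, which coats lipid droplets, fell by 0.52 ± 0.11, and Pparg, a lipid-sensing receptor, by 0.36 ± 0.08. With Cd68 these were the 3 falls among 18 genes of lipid uptake, storage and foam cells (4 adjusted over the list alone). The median was -0.05 (camera adjusted p = 0.0263; adjusted p = 0.238 with an estimated correlation). In the list of LXR targets, the genes of cholesterol efflux, Scd2, a fatty acid desaturase, rose by 0.53 ± 0.11, while Apoc2 and Cyp27a1 (-0.41 ± 0.09) fell; the 2 other Cyp27a1 probes read -0.34 and -0.32 without passing. Its median of 0.03 and mean of -0.25 differed in sign, with a downward camera direction (adjusted p = 0.433) and a fry adjusted p of 0.0228. The mean leaned on Apoc2, a neighbour of Apoe whose other probe read 0.38 without passing. Of 18 cholesterol synthesis genes 0 passed; Mvd, an enzyme of the mevalonate pathway, read 0.24 ± 0.10 (adjusted p = 0.249).

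Gclc, the catalytic chain of glutathione synthesis, fell by 0.62 ± 0.08 (adjusted p = 0.00439), the 1 fall among 16 NRF2 and oxidative stress genes (6 adjusted over the list alone). That list had a median of -0.12 (camera adjusted p = 0.0141; adjusted p = 0.152 with an estimated correlation). Of 20 inflammatory cytokine and chemokine genes, the chemokines Ccl3 (0.77 ± 0.15) and Ccl4 (0.62 ± 0.13) and the cytokine Il10 (0.75 ± 0.16) rose, 4 rose and 1 fell adjusted over the list alone, and camera gave no call (adjusted p = 0.595). Tlr4, the endotoxin receptor, fell by 0.52 ± 0.11, but its 2 other probes read -0.51 and -0.18 without passing. The Toll-like receptor list had a median of 0.10 and a mean of 0.01 with a downward camera direction (adjusted p = 0.929). In the interferon list Stat2 read -0.31 ± 0.09 (adjusted p = 0.11), as the best of 26 genes of which 0 passed. In 15 lists no gene passed and camera made no call, with medians between -0.10 and 0.08 over 246 members.

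On normal chow, 67 probes differed between ApoE-/- and Bl6 samples (n = 3 each), 25 up and 42 down (2762 at an unadjusted p under 0.05), naming 58 genes. Leaving out 1 array gave 26 (without sample 1) to 77 (without sample 4), and fitting only these groups 26. With the ApoE-/- diets as in the log2 table the count was 75, with 27 up and 48 down. Beyond Apoe and the sex-linked genes, the largest rises were in Gzmk (2.31 ± 0.25, detected on 2 of 3 Bl6 arrays), Pglyrp1 (1.68 ± 0.16) and Lrg1, a glycoprotein of neutrophil granules (1.49 ± 0.21). The largest falls were in Apoc2 (-3.46 ± 0.22), Psmd8 (-3.25 ± 0.12) and Clasrp (-2.76 ± 0.16). Zfp30 was undetected in all 3 Bl6 samples and at least 3.05-fold higher in the knockout, and Zfp420 was undetected in all 3 ApoE-/- samples and at least 4.81-fold lower there. Il10, an anti-inflammatory cytokine, rose by 1.40 ± 0.22 (adjusted p = 0.0272); with the diets exchanged it read 1.09 and did not pass (adjusted p = 0.103). Apoc1, a neighbour of Apoe and an LXR target, rose by 0.98 ± 0.15 (adjusted p = 0.0265; 0.0197 with the diets exchanged). Klk1 fell by 1.01 ± 0.17, and Cd177 rose by 1.18 ± 0.18 while its other probe did not pass.

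Of the 16 neutrophil genes on chow, 1 rose over all probes and 14 adjusted over the list alone, with a median of 0.87 (camera adjusted p = 3.1e-14; adjusted p = 0.115 with an estimated correlation). With the diets exchanged 2 rose and the median was 0.98. The plasmacytoid list had a median of -0.24 with 14 of 14 genes at or under 0 (camera adjusted p = 2.2e-05; adjusted p = 0.142 with an estimated correlation), and -0.14 with the diets exchanged (camera adjusted p = 0.00427; adjusted p = 0.449 with an estimated correlation). Camera also called the T cell list (median 0.45), the NK cell list (0.44) and the proliferation list (0.32) up. It called the B cell list (-0.36), the macrophage list (-0.19, mean -0.02) and the cholesterol synthesis list (-0.13) down. With an estimated correlation their adjusted p-values were 0.17, 0.631, 0.809, 0.309, 0.631 and 0.309. The NK call was lost with the diets exchanged, and the other 5 stayed under an adjusted p of 0.05, but not with an estimated correlation (0.292, 0.713, 0.56, 0.647 and 0.56). Sqle read -0.63 ± 0.17 (adjusted p = 0.185), Ciita 0.34 ± 0.13 (adjusted p = 0.388), Cd83 -0.46 ± 0.12 (adjusted p = 0.185) and Stat2 -0.41 ± 0.12 (adjusted p = 0.258). The LXR list had a median of 0.09 and a mean of -0.07, and the inflammatory list a median of -0.08 and a mean of 0.05; camera called neither. In 22 lists no gene passed and camera made no call (medians -0.11 to 0.15).

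On the high-cholesterol diet, 202 probes differed by genotype (n = 3 each), 74 up and 128 down (3476 at an unadjusted p under 0.05), naming 171 genes. The count fell to 38 without sample 10 and to 22 when only these groups were fitted; with the diets exchanged it was 112, with 40 up and 72 down. Rises were led, after the Y genes, by Dctn1, a chain of the dynein motor's partner (1.93 ± 0.33), Ltf (1.91 ± 0.35) and Lcn2, an iron-capturing protein of neutrophils (1.76 ± 0.34). Zfp30, detected on 1 of 3 Bl6 arrays, rose too (adjusted p = 2.2e-04). Lcn2 lost its call with the diets exchanged (1.57, adjusted p = 0.0716). Falls were led by Apoc2 (-3.74 ± 0.22), Psmd8 (-3.20 ± 0.12) and Clasrp (-2.23 ± 0.16) after Apoe and Xist; Zfp420 was undetected in all 3 ApoE-/- samples and at least 3.97-fold lower there. Mmp9, a matrix protease (1.17 ± 0.17), Cd177 (1.56 ± 0.18) and F13a1 (1.21 ± 0.24) rose, and F13a1 read 1.09 without passing when the diets were exchanged (adjusted p = 0.0769). Cd177's other probe read 0.93 and did not pass (adjusted p = 0.0739). Il1b, the cytokine interleukin 1 beta, rose by 0.85 ± 0.14, and by 0.86 with the diets exchanged (adjusted p = 0.0261 and 0.0329). Gclc fell by 0.89 ± 0.12 (adjusted p = 0.00662) and read -0.54 with the diets exchanged (adjusted p = 0.0723). Sqle, an enzyme of cholesterol synthesis, rose by 1.02 ± 0.17 (adjusted p = 0.0235). Its other probe read 0.35, and with the diets exchanged the value was 0.84 (adjusted p = 0.0546). Sqle read 8.02 to 8.13 in Bl6 high-cholesterol, 9.49 to 9.61 in Bl6 chow and 8.76 to 9.52 in ApoE-/- samples. Il1b read 10.17 to 10.55 in Bl6 high-cholesterol samples and 11.05 to 11.45 in all others. For both genes this contrast, the diet effect in Bl6 samples and the interaction rest on the same Bl6 arrays.

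On that diet 7 of 16 neutrophil genes rose (11 adjusted over the list alone), with a median of 1.20 (camera adjusted p = 6.8e-14; adjusted p = 0.0986 with an estimated correlation); with the diets exchanged 5 rose. Cholesterol synthesis genes had a median of 0.26, with 1 of 18 risen and 6 adjusted over the list alone (camera adjusted p = 6.3e-04; adjusted p = 0.0986 with an estimated correlation). Under exchange their median was 0.27 (adjusted p = 0.161 with an estimated correlation). Lists called down were the macrophage genes (median -0.45), the LXR targets (-0.20), lipid uptake and storage (-0.31), NRF2 (-0.11) and fatty acid oxidation (-0.16). With an estimated correlation their adjusted p-values were 0.19, 0.0986, 0.0986, 0.0986 and 0.295. The LXR list holds Apoc1 and Apoc2, which both lie near Apoe. T cell genes were called up (median 0.30; adjusted p = 0.295 with an estimated correlation). Fatty acid oxidation was no longer called when the diets were exchanged, while the type 2 dendritic cell, NK, MHC class II and interferon lists then were (medians 0.18, 0.38, -0.13 and -0.25; adjusted p = 0.136, 0.478, 0.404 and 0.512 with an estimated correlation). No list passed with an estimated correlation under exchange (lowest adjusted p = 0.107). As named, Ctss of the MHC class II list read -0.32 ± 0.14 (adjusted p = 0.343), Il15 -0.48 ± 0.12 (adjusted p = 0.112) and the RNA sensor Ddx58 -0.60 ± 0.22 (adjusted p = 0.261). The inflammatory list's median was -0.01 and its mean 0.11. In 22 lists nothing was called (medians -0.15 to 0.17).

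The calls of both diets overlapped in 36 probes, all in the same direction, 10 up and 26 down, where 0.0701 and 0.204 would overlap if drawn independently; both contrasts share the fit's estimate of spread. Under exchange 35 overlapped. By brightest probes these were 25 genes, of which 14 lay near Apoe (odds ratio 59.3, confidence interval 23.0 to 164, Fisher's exact two-sided p = 8.3e-17; 55.0 without Apoe itself). The 2 Y genes and Xist were among them, as were Pglyrp1, Cd177, Lrg1 and Zfp30. Outside chromosome 7, Aloxe3, a lipoxygenase, fell by 0.90 and 0.75 on chow and on the high-cholesterol diet, and Cbln1, a secreted synapse organiser, by 1.89 and 1.32; both were chosen after their values were seen. Across probes the genotype effects of both diets correlated with r = 0.32 (rho = 0.20), and probes are not independent replicates.

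The share of rises depended on the processing. Quantile-normalised values gave 25 rises and 42 falls on chow, median scaling 41 and 30, no background correction 101 and 124, and the deposited log2 values 210 and 67. On the high-cholesterol diet the splits were 74 and 128, 36 and 126, 264 and 368, and 357 and 285. Averaged over diets they were 172 and 251, 154 and 178, 542 and 596, and 1276 and 377. The log2 values differ in scaling and background correction at once, and on each diet also in the names of the ApoE-/- arrays. The log2 values under the intensity table's names gave 130 and 92 on chow and 706 and 243 on the high-cholesterol diet, where the median of all probes was shifted by 0.11.

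Diet changed 10 probes in Bl6 samples (n = 3 per diet), 6 up and 4 down (3155 at an unadjusted p under 0.05). They named 8 genes, and this contrast does not depend on which table names the knockout arrays. Sdc2, a cell-surface heparan sulfate proteoglycan, rose by 1.96 ± 0.21 (adjusted p = 0.00871) and Apoc1, an apolipoprotein, by 1.62 ± 0.15 (adjusted p = 0.00416). Sostdc1, an inhibitor of BMP and WNT signals that was detected on 1 of 3 chow arrays, rose as well (adjusted p = 0.0188). The transcriptional regulator Ripply3 rose by 1.26 ± 0.16 and the protease inhibitor Ctla2b by 0.92 ± 0.12; a second Apoc1 probe rose by 1.68. Falls were in Sqle (-1.47 ± 0.17, adjusted p = 0.00893), Cacna1d, a calcium channel chain (-0.99 ± 0.14, adjusted p = 0.0454), and Cyp51, a demethylase of sterol synthesis (-0.93 ± 0.13, adjusted p = 0.0412). Sqle's other probe read -0.87 and did not pass (adjusted p = 0.301). Most of these calls were lost when 1 of 4 arrays was left out: without sample 8, 9, 10 or 12 only 2 of the 10 probes were called, and of the 8 genes Apoc1 alone passed each time. Fitting only the groups compared called 4 probes, 3 of them shared. A split of the same arrays that does not follow diet, samples 7, 10 and 12 against 8, 9 and 11, called 169 probes. The B cell list's mean was higher on chow samples 8 and 9 and high-cholesterol sample 11 than on the others, so it was uneven over diet. Median scaling called 7 up and 2 down, and the log2 values 110 up and 111 down.

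**Figure D4:**
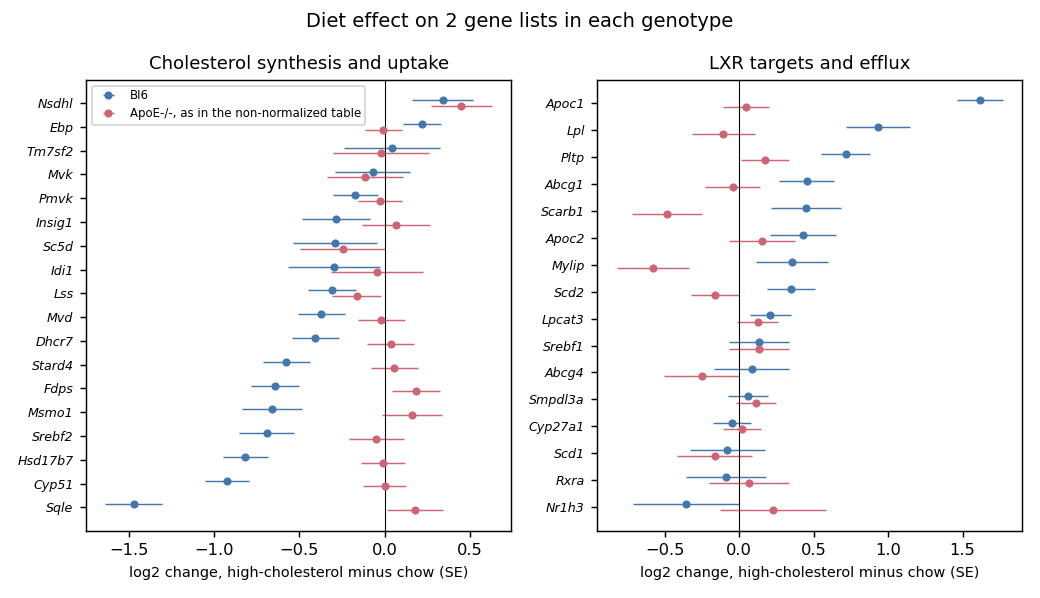
Diet effect (x axis, log2, high-cholesterol minus chow, with standard errors) on each measured gene (y axis) of the cholesterol synthesis and LXR lists, in Bl6 and in ApoE-/- samples as named in the intensity table. Sqle fell by 1.47 in Bl6 samples; with the ApoE-/- diets exchanged every ApoE-/- value changes sign.

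Cholesterol synthesis genes were lower on the high-cholesterol diet in Bl6 samples. Sqle and Cyp51 were the 2 falls among 18 genes, 9 fell adjusted over the list alone, and 15 of 18 lay below 0 and 3 above. Hsd17b7 read -0.82 ± 0.13 (adjusted p = 0.0774), Srebf2, the factor that drives the pathway, -0.69 ± 0.16 (adjusted p = 0.151) and Fdps -0.65 ± 0.14 (adjusted p = 0.143). The list's median was -0.34 (camera adjusted p = 3.0e-07; adjusted p = 0.0853 with an estimated correlation; fry adjusted p = 0.00164). LXR targets read the other way: Apoc1 rose, as 1 of 16 genes (3 adjusted over the list alone), Lpl, lipoprotein lipase, read 0.93 ± 0.21 (adjusted p = 0.148), Pltp 0.71 ± 0.16 (adjusted p = 0.148) and the cholesterol exporter Abcg1 0.45 ± 0.18 (adjusted p = 0.367). Their median was 0.28 (camera adjusted p = 4.2e-04; adjusted p = 0.109 with an estimated correlation; fry adjusted p = 0.0121).

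Camera called 7 further lists in Bl6 samples, in none of which a gene passed over all probes. Interferon genes had a median of 0.31 with 21 of 26 above 0 (adjusted p = 1.2e-04, and adjusted p = 0.52 with an estimated correlation). Their best gene, Oasl2, an antiviral protein, read 0.79 ± 0.24 (adjusted p = 0.239), and its other probe 0.22 (adjusted p = 0.741). Plasmacytoid genes had a median of -0.32 (adjusted p = 3.7e-04; adjusted p = 0.264 with an estimated correlation), and 4 of 14 fell adjusted over the list alone; Siglech, a receptor of these cells, read -0.78 ± 0.19 (adjusted p = 0.158). Lipid uptake genes (0.18; 2 of 18 rose adjusted over the list alone), fatty acid oxidation genes (0.10) and macrophage genes (0.08) were called up. B cell genes (-0.26) and immediate early and heat shock genes (-0.18) were called down. With an estimated correlation the adjusted p-values of these 5 were 0.305, 0.326, 0.537, 0.537 and 0.32. The B cell genes did not follow diet on every array: their mean was 10.28 and 10.07 on chow samples 8 and 9 but 9.63 on chow sample 7, and 9.92 on high-cholesterol sample 11. The macrophage mean of 0.26 was far from its median because Vsig4 read 3.56 ± 0.70 (adjusted p = 0.106). Il1b read -0.90 ± 0.14 (adjusted p = 0.0774), H2-Eb2 of MHC class II 0.24 ± 0.13 (adjusted p = 0.493) and the costimulator Icosl -0.29 ± 0.10 (adjusted p = 0.274). In 24 lists nothing was called (medians -0.25 to 0.16).

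In ApoE-/- samples limma called 0 probes between diets (n = 3 each), with 981 of 26390 at an unadjusted p under 0.05; the array-weighted fit called 1, and every direction turns around if the log2 table's names are right. Under the intensity table's names the best genes were Pth2, a neuropeptide (adjusted p = 0.081), the histone demethylase Kdm3b (1.17 ± 0.18, adjusted p = 0.395, detected on 1 of 3 chow arrays) and Col20a1, a collagen (0.69 ± 0.13, adjusted p = 0.628). Next came the odorant receptor genes Olfr1341 and Olfr48 (adjusted p = 0.628 and 0.634). Pth2 was undetected on the chow arrays and read at least 1.93-fold higher on the high-cholesterol diet; Olfr1341 and Olfr48 were undetected on the high-cholesterol arrays and read at least 1.58-fold and 1.78-fold lower. Pth2 and Olfr1341 were detected on 3 ApoE-/- arrays and on no Bl6 array. Cholesterol synthesis genes had a median of -0.01 and a mean of 0.02 with an upward camera direction (adjusted p = 0.829), and LXR targets a median of 0.03 and a mean of -0.05 with a downward one (adjusted p = 0.906). Nsdhl of sterol synthesis read 0.45 ± 0.18, H2-Ab1 -0.15 ± 0.10, Birc3 -0.20 ± 0.14, Il10 -0.32 ± 0.22 and the RNA sensor Ifih1 0.59 ± 0.21, each with an adjusted p = 1. Mylip, which degrades the LDL receptor, was detected on 2 of 3 chow arrays and on no high-cholesterol array, at least 1.34-fold lower there (adjusted p = 1). The 3 other Nsdhl probes read 0.33, 0.04 and -0.15, and the 2 other H2-Ab1 probes 0.02 and 0.13. Kdm3b's other probe read 0.55 without passing.

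Camera called 2 lists between those diets. NK cell genes had a median of -0.21 with 16 of 16 below 0 (adjusted p = 0.00311; adjusted p = 0.951 with an estimated correlation), and type 1 dendritic cell genes -0.09 (adjusted p = 0.0427; adjusted p = 0.951 with an estimated correlation). Under exchange the medians were 0.21 and 0.09. No member passed adjusted over the list alone. In the other 31 lists medians lay between -0.07 and 0.14. Across probes, the diet effects of both genotypes correlated with r = -0.004, or 0.004 with the diets exchanged.

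The interaction asks whether diet acted differently in the knockout, whose arrays also differed from Bl6 in the sex-linked genes. Limma called 0 probes, with 2006 at an unadjusted p under 0.05 (0 and 1962 with the diets exchanged); without background correction the count was 10, with a variance trend and robust estimation 13, and with the log2 values 8. The best genes were Apoc1 (-1.57 ± 0.22), Sqle (1.65 ± 0.23), Sdc2 (-2.03 ± 0.30), Ripply3 (-1.53 ± 0.23) and Ctla2b (-1.07 ± 0.17), each with an adjusted p = 0.105. With the diets exchanged they read -1.66, 1.30, -1.89, -0.99 and -0.77, with adjusted p-values of 0.105, 0.388, 0.2, 0.468 and 0.459. Each of these genes also changed with diet in Bl6 samples, whose arrays are part of this contrast. Apoe itself read -0.82 ± 0.20 (adjusted p = 0.389). Others named were Il1b (0.89 ± 0.20, adjusted p = 0.346), Icosl (0.34 ± 0.14, adjusted p = 0.595), Oasl2 (-0.85 ± 0.34, adjusted p = 0.593) and H2-Ab1 (-0.24 ± 0.15, adjusted p = 0.746). Oasl2's other probe read -0.32.

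Camera called 5 lists for the interaction. Cholesterol synthesis genes had a median difference of 0.35 with 15 of 18 above 0 (adjusted p = 1.1e-06; adjusted p = 0.108 with an estimated correlation), and 7 had a positive difference adjusted over the list alone. Under exchange the median was 0.43 (adjusted p = 1.2e-05; adjusted p = 0.196 with an estimated correlation). LXR targets had -0.31 (adjusted p = 0.00188; adjusted p = 0.138 with an estimated correlation), and -0.18 under exchange (adjusted p = 0.01; adjusted p = 0.292 with an estimated correlation). Plasmacytoid genes had 0.55 (adjusted p = 6.0e-05; adjusted p = 0.138 with an estimated correlation), B cell genes 0.34 (adjusted p = 0.012; adjusted p = 0.771 with an estimated correlation) and lipid uptake genes -0.22 (adjusted p = 0.00352; adjusted p = 0.138 with an estimated correlation). Camera called none of these last 3 under exchange, but did call interferon (-0.37) and immediate early genes (0.21; adjusted p = 0.512 and 0.461 with an estimated correlation). In 28 lists nothing was called (medians -0.23 to 0.32).

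Averaged over genotypes, limma called 0 probes for diet, with 1962 at an unadjusted p under 0.05 (0 and 2006 with the diets exchanged); the count was 3 without background correction, 9 with a variance trend and robust estimation, and 8 with the log2 values. The best genes were Apoc1 (0.83 ± 0.11, adjusted p = 0.105), Ficd (adjusted p = 0.196), Kdm3b (0.84 ± 0.13, adjusted p = 0.196), Sostdc1 (0.88 ± 0.14, adjusted p = 0.2) and Sdc2 (0.95 ± 0.15, adjusted p = 0.2). Ficd was undetected on all 6 high-cholesterol arrays and read at least 1.34-fold lower there, but its other probe read -0.09 (adjusted p = 0.887). With the diets exchanged the other 4 genes read 0.79, -0.32, 0.73 and 1.02. Sostdc1 was undetected on most Bl6 chow arrays and Kdm3b on most ApoE-/- chow arrays, so the values of both are not exact. Another Kdm3b probe read 0.34 without passing. Sqle read -0.65 ± 0.12, Il1b -0.45 ± 0.10, Ifih1 0.56 ± 0.15, Fscn1, an actin bundler of mature dendritic cells, 0.23 ± 0.12, and H2-Eb2 0.14 ± 0.09, with no adjusted p under 0.388. Cholesterol synthesis genes had a median of -0.21 (camera adjusted p = 1.2e-05; adjusted p = 0.196 with an estimated correlation) and LXR targets 0.09 (camera adjusted p = 0.01; adjusted p = 0.292 with an estimated correlation). Interferon genes had 0.18 (camera adjusted p = 4.6e-06; adjusted p = 0.512 with an estimated correlation) and immediate early genes -0.10 (camera adjusted p = 0.0243; adjusted p = 0.461 with an estimated correlation). Under exchange, cholesterol synthesis genes had -0.18 and LXR targets 0.15, and camera called both again, with an adjusted p = 0.108 and 0.138 with an estimated correlation. It then also called plasmacytoid genes (-0.27), B cell genes (-0.17) and lipid uptake genes (0.11; adjusted p = 0.138, 0.771 and 0.138 with an estimated correlation), but neither interferon nor immediate early genes. In the other 29 lists medians lay between -0.18 and 0.09.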

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

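Camera and fry on the interaction were planned, and the tests of exchanged diets and of spread were chosen only after the result was seen. A difference between the genotypes in the effect of diet, with a camera adjusted p under 0.05, drew attention to 5 lists. Cholesterol synthesis genes had a median interaction of 0.35, LXR targets -0.31, lipid uptake and foam cell genes -0.22, plasmacytoid genes 0.55 and B cell genes 0.34. With an estimated correlation the adjusted p-values were 0.108, 0.138, 0.138, 0.138 and 0.771, and no single gene passed for the interaction. The medians of the diet effect were -0.34, 0.28, 0.18, -0.32 and -0.26 in Bl6 samples and -0.01, 0.03, -0.07, 0.14 and 0.03 in ApoE-/- samples.

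Cholesterol synthesis genes were lower on the high-cholesterol diet in Bl6 and not in ApoE-/- samples, and an exchange of the ApoE-/- diets in 1 of the tables could be a cause. A larger spread between the ApoE-/- arrays could also hide an equal effect there. In Bl6 samples the mean of the list per array differed between diets by -0.411 (confidence interval at R's default level -0.500 to -0.321), and in ApoE-/- samples by 0.0238. The interval of the ApoE-/- difference had a lower bound of -0.1758, above the Bl6 interval, so a fall of the Bl6 size lay outside it. With the diets exchanged the lower bound was -0.2235, again above the Bl6 interval. This is the same interval with its sign turned, not a second test. The median SD within groups of the list's genes was 0.170 in ApoE-/- and 0.151 in Bl6 samples. The list was examined because its interaction was called, and camera with an estimated correlation called that interaction under neither naming. The ApoE-/- interval therefore argues against both causes but excludes neither. A smaller effect in ApoE-/- samples stays possible within these bounds. Sex went with genotype on every array, so a sex difference in the effect of diet cannot be told apart from one of the knockout.

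Plasmacytoid, B cell and lipid uptake genes lost their camera calls when the ApoE-/- diets were exchanged, with adjusted p-values of 0.0643, 0.144 and 0.29. What set them apart was not tested further.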

How the results depend on the processing

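Exchanging the ApoE-/- diets, and using the log2 values under the intensity table's names, were chosen only after the data were seen; the cause of each shift was not tested. A chip block was not run because the files name no chip. None of the named genes that passed changed its sign under the alternatives that were run for it, but calls were lost: in 236 gene results when 1 array was left out (628 kept), and in 18 with only the groups compared (24 kept).

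Counts of called probes are given for genotype on chow, genotype on the high-cholesterol diet, diet in Bl6, interaction, genotype averaged and diet averaged (67, 202, 10, 0, 423 and 0). Without background correction they were 225, 632, 266, 10, 1138 and 3. From the log2 table they were 277, 642, 221, 8, 1653 and 8, and under the intensity table's names 222, 949, 221, 8, 1653 and 8. A variance trend with robust estimation gave 239, 676, 254, 13, 1137 and 9. The stricter filter gave 107, 305 and 41, then 642 for genotype averaged and 1 for diet averaged. Fitting only the groups compared gave 26, 22 and 4 for the first 3. Array weights called 1 probe for diet in ApoE-/- samples, and exchanging the diets 112 for genotype on the high-cholesterol diet. With probes averaged per gene, 1 gene was called for diet in ApoE-/-, 22 in Bl6 and 1 for diet averaged. Of 49 list calls, 0 were left with an estimated correlation and 28 with fry, which called 30 lists in all; the log2 table gave 88, and 84 under the intensity table's names.

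Leaving out 1 array at a time gave 26 to 77 probes for genotype on chow, 38 to 157 on the high-cholesterol diet, 2 to 41 for diet in Bl6, 142 to 605 for genotype averaged, 0 throughout for the other comparisons, and 44 to 56 lists. On chow the count was 26 without sample 1, 27 without 2, 43 without 8 and 30 without 9. On the high-cholesterol diet it was 97 without sample 1, 130 without 2, 122 without 3, 49 without 4, 85 without 5, 90 without 6, 116 without 8, 38 without 10, 61 without 11 and 49 without 12. For diet in Bl6 it was 6 without sample 1, 20 without 7, 2 without 8, 2 without 9, 2 without 10, 41 without 11 and 2 without 12. For genotype averaged it was 142 without sample 1, 166 without 2, 267 without 3, 280 without 5, 215 without 6, 220 without 8, 200 without 9, 177 without 10, 197 without 11 and 230 without 12. Apoe for diet in ApoE-/- samples read 0.211 without sample 2 and -0.00718 without sample 3.

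Diet values in ApoE-/- samples turned their sign with the log2 table: Apoe -0.0816, Nsdhl -0.23, Mylip 0.11, H2-Ab1 0.0651, Birc3 0.10, Il10 0.0861, Ifih1 -0.32, Pth2 -0.486, Kdm3b -0.42, Col20a1 -0.31, Olfr1341 0.17 and Olfr48 0.26. Mylip, Pth2, Olfr1341 and Olfr48 were undetected in 1 of these groups, so their values here and below give a direction only. Averaged over genotypes Ifih1 read -0.0416 and Kdm3b -0.136. With the diets exchanged the ApoE-/- values were Apoe -0.0699, Nsdhl -0.45, Mylip 0.58, H2-Ab1 0.15, Birc3 0.20, Il10 0.32, Ifih1 -0.59, Pth2 -1.16, Kdm3b -1.17, Col20a1 -0.69, Olfr1341 0.80 and Olfr48 1.004. H2-Ab1 read 0.0572 for the interaction, and averaged over genotypes Ifih1 read -0.0386 and Kdm3b -0.324. The lists of conventional DC type 1 markers and NK cell markers turned upward between the diets of ApoE-/- samples, with adjusted p-values of 0.00177 and 2.91e-08 in the log2 table and 0.0427 and 0.00311 with the diets exchanged (both 0.951 with an estimated correlation).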

Other observations

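The splits of samples and the test of the chromosome 7 segment were written before the results, and the other tests here were chosen only after the result was seen. Apoc2, Psmd8 and Clasrp, near Apoe, fell in ApoE-/- samples on 1 probe each, with values of -3.60, -3.22 and -2.49, while another probe read 0.38, 0.25 and -0.06. Mrps12, also near Apoe, fell on both of its probes, by 0.98 and 1.18, and Nfkbib rose by 1.11.

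Genes changed by genotype in both diets lay near Apoe with an odds ratio of 59.25, which fits a chromosome 7 segment carried from the strain in which the knockout was made. A sex difference would not gather around Apoe, so the lower bound of 23.05 argues against sex as the cause of the gathering as a whole. Sex went with genotype on every array, so it cannot be excluded for any single gene near Apoe. Strain variants under single probes could still produce some of these calls. Of the genes near Apoe that changed and had other tested probes, 9 of 17 had none called alike, against 66 of 85 elsewhere (odds ratio 0.328, Fisher's exact two-sided p = 0.0665), so such variants cannot be told apart from changes in RNA. Sequencing the RNA, with reads assigned to strain, would separate them.

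Neutrophil genes such as S100a8 (1.10), Camp (1.68) and Ltf (1.76) may be higher because the ApoE-/- samples held more neutrophil RNA, although the cells were selected with CD11c beads, which should remove most neutrophils. The list's genes varied together within groups, with a mean correlation of 0.274 at percentile 100 of 10000 random lists (median -0.005, upper bound 0.0817). Random lists were matched on mean expression alone. Genes regulated together within the cells would also exceed them, so this does not single out neutrophil RNA. A lower share of the main cell type would raise genes of the other cell types. The macrophage list had a median of -0.29, but its mean per array in ApoE-/- samples overlapped that in Bl6 chow samples. Macrophages can also change on their own, and the T and NK cell lists were called up. A lower share of the main cell type is therefore not excluded. Sex went with genotype on 12 arrays, so its part cannot be told apart from the knockout's. Counting Ly6G+ cells in CD11c+ fractions from littermates of both sexes would test both.

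In splits of the same 6 arrays into other groups of 3, the real genotype split on chow ranked 1 of 10 (67 probes, highest other 0) and that on the high-cholesterol diet 1 of 10 (202, highest other 0). For diet in Bl6 samples 2 of 10 splits called as many (10; highest other 169), and for diet in ApoE-/- samples 10 of 10 (0; highest other 34). The number of 10 splits is too few for a share under 0.05. The split of samples 7, 10 and 12 against 8, 9 and 11 called 169 probes, and that of 1, 2 and 6 against 3, 4 and 5 called 34. This is a structure among the samples that diet does not follow. The B cell list's mean parted along the first split (9.63, 9.63 and 9.61 against 10.28, 10.07 and 9.92). The macrophage list's mean parted along the second (10.86, 10.90 and 10.89 against 11.19, 11.03 and 11.14). Both lists were picked after their values were seen, and the neutrophil list's mean parted along neither. Whether cell content made these splits was not tested. Of 100 drawn splits, 1, the real one, called at least as many probes as genotype averaged over diets (423, highest other 2). All 100 did so for the interaction (0, highest other 47) and for diet averaged over genotypes (0, highest other 47). Every split reaches a real count of 0, so these shares say nothing on chance. The same holds for the 10 of 10 for diet in ApoE-/- samples.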
